A study of Mus musculus with 9 samples.

How the data were processed

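The 9 libraries were prepared from total RNA with a stranded mRNA kit (TruSeq), per the labels' protocols. The submitters' processing notes name FastQC, STAR, featureCounts and Subread and the build mm10, without versions, and the annotation release and strand setting of the counting are not given in the sources used here. Genes are listed by symbol, and the table holds raw counts per gene as deposited by the authors, whole numbers for 24421 symbols in 9 columns, with total counts of 27242168 to 45810089 per library. No mitochondrially encoded gene is in the table, so 27 of the 28 gene lists could be tested. One column name differs from its sample title in its last character; it was taken as the SHP099 replicate 3 sample, the sole one of that genotype, number and treatment.

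Groups were taken from the labels. Mutant cultures came from individual mice per the series description; for the WT cultures the labels name no individual mice, and p-values measure the spread between these samples. Replicate libraries differed by more than sampling noise in every group, with chi-square per degree of freedom of 11.1 to 116, so none looked like 1 library deposited more than once; this does not tell separate cultures from separate preparations of 1 culture. Replicate numbers come from the sample titles. The deviations of mutant vehicle and SHP099 libraries of the same number from their group means correlated at 0.54, 0.6 and 0.56 across genes, and those of different numbers at -0.36 to -0.23, so the numbers pair these libraries.

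Counts were analysed in R 4.3.3 with edgeR 4.0.16. filterByExpr by group (minimum count 10) kept 13270 genes and left out 11151, library sizes were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 9 libraries, so that the groups share 1 estimate of the spread. The 3 contrasts were SHP099 against vehicle in mutant cells, mutant against WT vehicle cells, and SHP099-treated mutant against WT vehicle cells. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, and 0.05 was the threshold. Errors of log2 fold changes are standard errors, the absolute log2 fold change divided by the square root of F. Levels are CPM on TMM-scaled library sizes as mean ± SD, and principal components used log2 CPM with a prior count of 2. The biological coefficient of variation was 9.04%.

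Gene lists for signalling, cell cycle, metabolism, stress and cell types were fixed before the data were examined. They were tested with camera in limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists), with camera's estimated correlation and with fry, which asks whether a list's genes move one way without comparing them with other genes. No list passed with an estimated correlation in the SHP099 or genotype comparison. Genes were named by a rule also fixed then: Ptpn11, Flt3 and Tet2 in each case; for SHP099 and for genotype the 10 largest increases and 10 largest decreases among called genes with at least 5 CPM in the higher group and no overlap between the 3 libraries of each group, leaving out predicted gene models and RIKEN clones; and up to 4 members with the smallest p of each list that passed camera or had at least 3 called members. Not every gene this rule takes is reported here.

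Coordinates, transcript lengths (longest coding transcript) and GC content were taken from GENCODE M21 on GRCm38, the assembly also called mm10; 23384 of the 24421 symbols matched and 23376 had a length. A smooth trend of log2 deviation on length and GC content (lowess span 0.3) was removed per library as an alternative. To see what shared vehicle libraries give, 20 sets of counts with no effect were simulated. The covariance was also taken from log2 CPM with no vehicle library in both comparisons, in 3 ways, a test chosen after seeing the data.

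The alternatives were DESeq2 size factors (RLE) in edgeR, DESeq2 1.42.0, no low-count filter, at least 1 CPM in at least 3 libraries, each library left out in turn, the replicate number as a block, a fit of the 2 compared groups alone, and other list tests. The corrections for length and GC content, the block combined with an estimated correlation, and the tests of gene families were chosen after seeing the data. The scripts were tested on simulated data with 200 changed genes among 13270, in 5 draws. For SHP099 against vehicle, 61.6% of genes changed by 0.5 log2 units and 78.2% of those changed by 1 were recovered, with 5.16% of calls false. With the block these were 55.6%, 79.4% and 12.8%, more false calls than the nominal 5%. The simulated libraries were drawn independently, without pairing. The share of false calls with the block in the real, paired libraries is therefore not known from this. For mutant against WT the shares were 61%, 78.2% and 5.88%, and for treated mutant against WT 61%, 82.4% and 6.39%. Of the lists, 2 passed where 1 had been raised, the raised one among them. An artificial length trend gave 1842 calls, and 3 after its removal.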

Results

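Bulk RNA sequencing was carried out on myeloid blast-like mouse cells grown for 5 days from lineage-depleted bone marrow in interleukin 3, interleukin 6 and stem cell factor. The 9 libraries fall into 3 groups of 3. Wild-type (WT) cells received vehicle. Cells from Tet2-/-Flt3ITD mice, labelled as lacking the DNA demethylase gene Tet2 and carrying an internal tandem duplication in the receptor tyrosine kinase gene Flt3, received vehicle or SHP099 for 24 h. SHP099 is an allosteric inhibitor of SHP2, the tyrosine phosphatase encoded by Ptpn11 that links growth factor receptors to RAS and ERK. The mutant cultures were established from individual mice. Total counts per library ran from 27242168 to 40681117 in WT cells, from 30982845 to 41567622 in mutant vehicle cells and from 41053983 to 45810089 in SHP099-treated cells.

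Tet2 (chromosome 3, 133463679 to 133545139, GRCm38) was measured first as a check of the labels. It stood at 33.2 ± 1.48 CPM (counts scaled to library size; SD, n = 3) in WT cells, 15.5 ± 1.3 CPM in mutant vehicle cells and 12.4 ± 1.28 CPM in SHP099-treated cells, and every mutant library lay below every WT library (log2 fold change -1.10 ± 0.09 for mutant against WT vehicle, SE; edgeR adjusted p = 0.00013). That left 0.467 of the WT level, and counts per gene do not show which part of the gene is deleted. With SHP099 Tet2 changed by a further -0.32 ± 0.09 (adjusted p = 0.029), a call that 3 of the 9 fits with 1 library left out, the fit of the 2 groups alone and both corrections for transcript length lost, with adjusted p values from 0.00052 to 0.4 over all alternatives. Ptpn11 (chromosome 5, 121130533 to 121191397), the gene of the drug's target, was at 295 ± 32 CPM with vehicle and 299 ± 18.9 CPM with SHP099, a log2 fold change of 0.02 ± 0.08 (SE; edgeR adjusted p = 0.87). With the replicate number as a block and the transcript length trend removed, the adjusted p for Ptpn11 was 0.019. Between mutant and WT vehicle cells it changed by -0.26 ± 0.08 (adjusted p = 0.033), a call lost in 4 fits with 1 library left out and with the block (adjusted p 0.0037 to 0.1 over the alternatives). Flt3 (chromosome 5, 147330741 to 147400489) was low in all groups, at 1.92 ± 0.505 CPM in WT and 2.19 ± 0.703 CPM in mutant vehicle cells, and the counts per gene do not show the duplication. The first principal component held 43.3% of the variance of log2 CPM and separated WT from mutant libraries, and the second held 14.6% and separated SHP099 from vehicle in the mutant cells.

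The comparison of SHP099 with vehicle asks what the inhibitor does to gene expression in leukemic myeloid cells. After 24 h, 10 of 22 genes that RAS-ERK signalling switches on were lower, as were 28 of 42 nucleolar and growth genes that are targets of the transcription factor MYC. Some genes of mature neutrophils (5 of 17), monocytes (3 of 21), mast cells (5 of 17) and megakaryocytes (2 of 11) were higher. Bulk libraries do not tell a change in the share of such cells from a change of expression within cells. Dusp6, a phosphatase that feeds back on ERK, went from 45.9 ± 2.32 to 29.7 ± 0.333 CPM (1.55-fold lower). Fcer1a, a chain of the high-affinity IgE receptor, went from 20.5 ± 3.39 to 51.4 ± 7.68 CPM. Of 13270 genes tested with edgeR's quasi-likelihood test, 2890 passed an adjusted p of 0.05, 1169 higher and 1721 lower, and 75 of them changed more than 2-fold. The median absolute log2 fold change of the called genes was 0.27. Vehicle and SHP099 libraries with the same number deviated together, and with that number as a block 5563 genes passed, 2791 higher and 2772 lower, including 2883 of the 2890. Without SHP099 replicate 3 the count was 1767.

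Among RAS-ERK output genes, 10 of 22 measured members fell, none rose, and the list passed camera (adjusted p = 1.1e-04; adjusted p = 0.40 with an estimated correlation). Adjusted over the list alone, 11 fell and 1 rose. Dusp6 fell by 0.63 ± 0.07 (SE) on the log2 scale, Spred2, an inhibitor of RAS signalling, by 0.62 ± 0.07, the transcription factor gene Etv5 by 0.89 ± 0.13, and Spry4, another feedback inhibitor, by 1.10 ± 0.22. Their edgeR adjusted p values ran from 0.00053 to 0.0066. Spry4 was low, at 1.87 ± 0.238 CPM with vehicle and 0.867 ± 0.179 CPM with SHP099. With the transcript length trend removed in the blocked fit, 15 of the 22 were lower and 1 higher.

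Of MYC target genes, 28 of 42 measured members were lower and none higher (camera adjusted p = 4.9e-17; adjusted p = 0.40 with an estimated correlation), and 30 were lower adjusted over the list alone. The ribosome biogenesis genes Mybbp1a, Utp20 and Tcof1 changed by -0.50 ± 0.04, -0.63 ± 0.06 and -0.47 ± 0.04, and Cad, which encodes the enzyme that starts pyrimidine synthesis, by -0.71 ± 0.07 (log2, SE). Mdn1, which encodes an AAA ATPase of ribosome assembly, changed by -0.84 ± 0.08 and was among the 10 largest decreases by the naming rule. In the same direction, 3 of 8 heat shock genes fell (camera adjusted p = 0.011; adjusted p = 0.40 with an estimated correlation), with the same 3 of 8 called as a count adjusted over the list alone. They were Hsp90aa1 (-0.34 ± 0.04), Hsph1 (-0.29 ± 0.05) and Hspa1b (-0.56 ± 0.14), and Hspa1b has a near-identical neighbour, Hspa1a, so its counts are uncertain. The Hspa1b call was lost without mutant vehicle replicate 2 or 3 and without any SHP099 replicate (adjusted p up to 0.066), and the blocked fit called 5 of the 8 lower.

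Of mature neutrophil genes, 5 of 17 rose and none fell (camera adjusted p = 3.6e-05; adjusted p = 0.40 with an estimated correlation), 8 adjusted over the list alone and 16 in the blocked fit. S100a9, a calcium-binding protein abundant in neutrophils, went from 7600 ± 351 to 11000 ± 1030 CPM, and Ngp, a neutrophil granule gene, changed by 0.82 ± 0.19 (log2, SE). With the length trend removed in the fit of all libraries the adjusted p of S100a9 was 0.091. Mast cell and basophil genes rose in 5 of 17 members (camera adjusted p = 0.00015; adjusted p = 0.43 with an estimated correlation; 5 adjusted over the list alone), and 12 were higher in the blocked fit. Fcer1a changed by 1.33 ± 0.19, Cpa3, a mast cell protease gene, by 0.77 ± 0.11, and Ms4a2, the IgE receptor beta chain, by 0.54 ± 0.12. Monocyte and macrophage genes rose in 3 of 21 members, all 3 also adjusted over the list alone (camera adjusted p = 0.007; adjusted p = 0.51 with an estimated correlation). The blocked fit called 16 of these higher and 1 lower. Ly6c2 changed by 0.61 ± 0.09 and Cx3cr1 by 1.20 ± 0.23. Among 11 megakaryocyte genes, Pf4 (0.52 ± 0.11) and Gp1bb (0.63 ± 0.15) rose, 6 did adjusted over the list alone and 10 in the blocked fit (camera adjusted p = 0.00097; adjusted p = 0.63 with an estimated correlation). With the length trend removed in the fit of all libraries the adjusted p of Pf4 was 0.057. Without mutant vehicle replicate 2 or without SHP099 replicate 1, 6 were higher.

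Oxidative phosphorylation genes were the eighth list to pass camera, with 7 of 27 members higher, 9 adjusted over the list alone (adjusted p = 0.0015; adjusted p = 0.64 with an estimated correlation), and 12 higher and 1 lower in the blocked fit. Ndufa1 changed by 0.41 ± 0.08 and Cox5a by 0.27 ± 0.05 (adjusted p = 0.15 with the length trend removed in the fit of all libraries). The named members have short transcripts, and with the length trend removed in the blocked fit 6 were higher and 5 lower (adjusted p = 0.79). The 19 other lists did not pass. Among STAT5 targets, Pim2 (0.45 ± 0.05), Il2ra (1.72 ± 0.36), Socs1 (0.39 ± 0.09) and Bcl2l1 rose while Ccnd2 fell by 0.59 ± 0.06 (camera adjusted p = 0.15). Il2ra was low, at 0.52 ± 0.226 CPM with vehicle and 1.68 ± 0.639 CPM with SHP099. Of cholesterol synthesis genes, 6 of 23 rose (adjusted p = 0.17), of interferon response genes 4 rose and 1 fell (adjusted p = 0.10), and of ATF4 stress and amino acid genes 1 rose and 4 fell (adjusted p = 0.53). G1/S genes had 3 lower of 25 and none higher (adjusted p = 0.36), and G2/M genes 6 lower and 2 higher of 24 (adjusted p = 0.17). The SHP2, receptor and RAS pathway list had 3 higher and 3 lower of 29 (adjusted p = 0.53), with Mapk3 at 0.40 ± 0.07 and Cbl at -0.54 ± 0.09. NF-kB genes had 1 higher and 2 lower (adjusted p = 0.71) and p53 targets 2 higher and 1 lower (adjusted p = 0.53). At most 1 member in each direction was called among pro-survival BCL2 family (adjusted p = 0.17), pro-apoptotic BCL2 family (0.52), primary granule (0.17), stem and progenitor (0.47), eosinophil (0.44), erythroid (0.53), dendritic cell (0.53), lymphoid (0.051), stromal (0.71) and glycolysis genes (0.75). Adjusted over the list alone, these counts were the same except for G1/S (0 higher, 2 lower), G2/M (3 and 8), NF-kB (1 and 1), cholesterol (6 and 1) and SHP2 pathway genes (3 and 2).

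Several of these counts depended on single libraries. Without SHP099 replicate 3, G2/M genes had 0 higher and 2 lower, interferon response genes 2 and 1, ATF4 stress genes 0 and 3, SHP2 pathway genes 1 and 1, p53 targets 0 and 2, and stem and progenitor genes 0 and 0. There interferon response, cholesterol synthesis (4 higher) and lymphoid genes passed camera (adjusted p = 0.03, 0.031 and 0.023). Without mutant vehicle replicate 1, interferon response genes had 1 and 1, p53 targets 0 and 1 (3 and 0 without SHP099 replicate 1) and SHP2 pathway genes 1 and 2, and lymphoid genes passed (adjusted p = 0.028). Primary granule genes passed without mutant vehicle replicate 3 or SHP099 replicate 2 (adjusted p = 0.044 and 0.024). NF-kB genes had 4 higher and 1 lower without mutant vehicle replicate 2, and 0 and 3 without mutant vehicle replicate 1. Stem and progenitor genes had 3 and 1 without mutant vehicle replicate 2, and eosinophil genes 0 and 2 without mutant vehicle replicate 1.

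In the blocked fit more members of 17 of these lists were called, and none of the 19 passed camera there. Stromal (0 and 0) and glycolysis genes (0 higher, 1 lower) kept their counts. Interferon response genes had 11 higher and 2 lower, SHP2 pathway genes 10 and 5, cholesterol synthesis genes 8 and 3, STAT5 targets 6 and 1, stem and progenitor genes 6 and 3, p53 targets 6 and 3, erythroid genes 6 and 2, and primary granule genes 5 and 0. G1/S genes had 2 higher and 8 lower, G2/M genes 3 and 9, NF-kB genes 3 and 6, ATF4 stress genes 2 and 6, dendritic cell genes 0 and 5 and eosinophil genes 1 and 3. Pro-survival BCL2 family genes had 3 higher, pro-apoptotic ones 2 and lymphoid genes 2, with none lower. With the length trend also removed, SHP2 pathway genes had 14 higher and 3 lower and passed camera (adjusted p = 0.014).

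**Figure D1:**
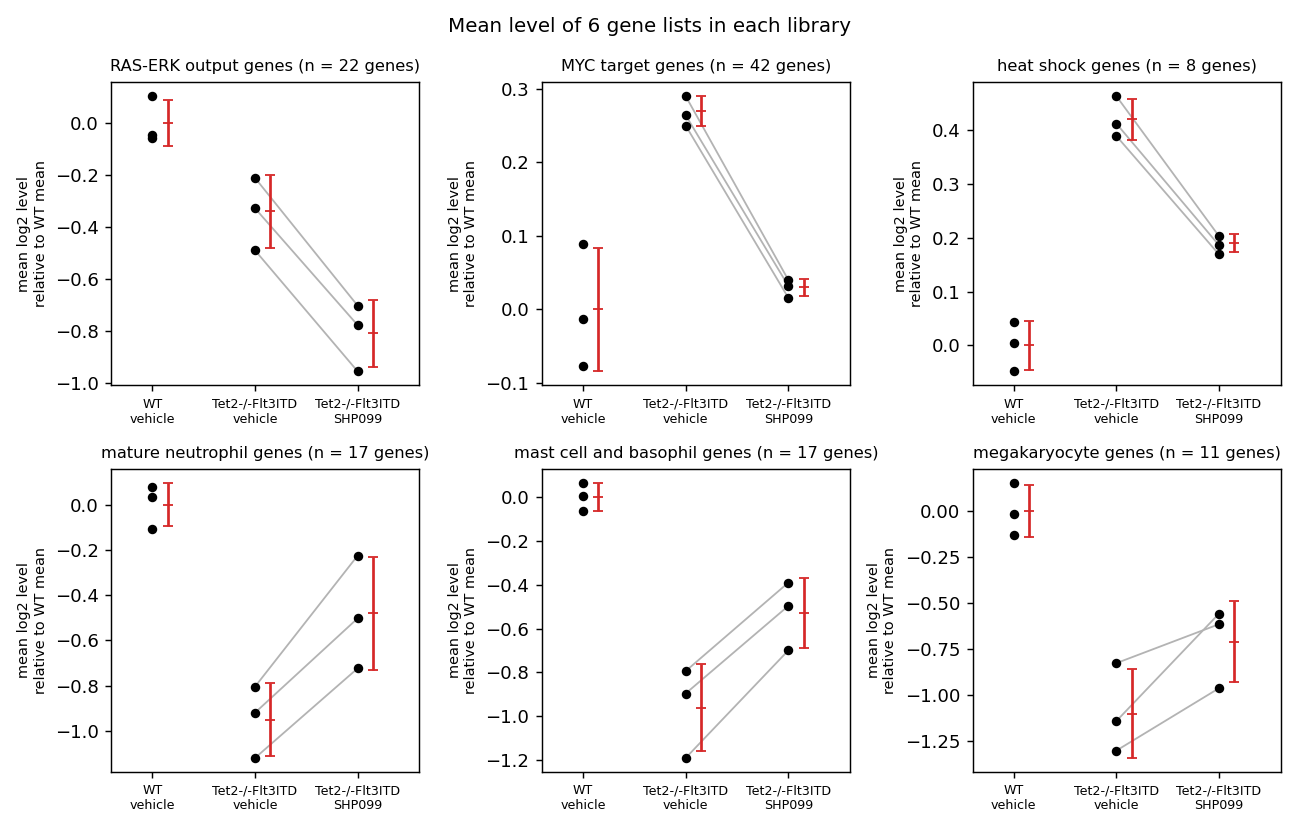
Mean log2 level of 6 gene lists in each library, relative to the WT mean. Points are libraries, grey lines join mutant vehicle and SHP099 libraries of the same number, and red marks are group means ± SD (n = 3). RAS-ERK output genes stood at -0.34 ± 0.14 with vehicle and -0.81 ± 0.13 with SHP099, and MYC targets at 0.27 ± 0.02 and 0.03 ± 0.012.

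The 10 largest increases by the naming rule were led by Rn45s, the 45S ribosomal RNA precursor, Mcpt2, a mast cell protease gene with close relatives, and Csrp3, a LIM domain gene. Mcpt2 went from 12.2 ± 6.49 to 42.9 ± 13.7 CPM (log2 fold change 1.84 ± 0.33) and Csrp3 went from 2.87 ± 0.623 to 8.14 ± 0.971 CPM. The largest decreases included the nuclear long noncoding RNA Malat1 (-1.13 ± 0.16), Snord22, a small nucleolar RNA that lies within a host gene (-1.05 ± 0.15), Vasn (-1.04 ± 0.13) and Gem (-0.93 ± 0.19). Rn45s made up 0.377% to 0.705% of counts in WT libraries and 0.276% to 0.357% in mutant vehicle libraries. In SHP099 replicates 2 and 1 the share was 0.658% and 0.734%, and WT replicate 1, without the drug, lay between them. SHP099 replicate 3 had 4.33% (95% Wilson interval 4.32% to 4.33%, counting error only). Whether these shares follow the level of the precursor in the cells was not tested. The log2 fold change of Rn45s with SHP099 was 2.71 ± 0.67 (edgeR adjusted p = 0.019) and 1.206 without SHP099 replicate 3. The call was lost without mutant vehicle replicate 1, 2 or 3 (adjusted p = 0.0563, 0.0532 and 0.0619; 6.9e-07 to 0.062 over the alternatives).

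Direction also went with transcript length. Among the 2561 genes with the shortest transcripts (61 to 1695 nucleotides), 460 were higher and 96 lower with SHP099, and among the 2558 with the longest (5001 to 123179 nucleotides), 32 were higher and 798 lower. Across 12801 genes, which are not independent replicates, Spearman's correlation of log2 fold change with transcript length was -0.338, and -0.301 without SHP099 replicate 3. With a smooth length and GC trend removed in each library, 2202 genes passed, 1003 higher and 1199 lower, and 5242 did in the blocked fit.

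**Figure D2:**
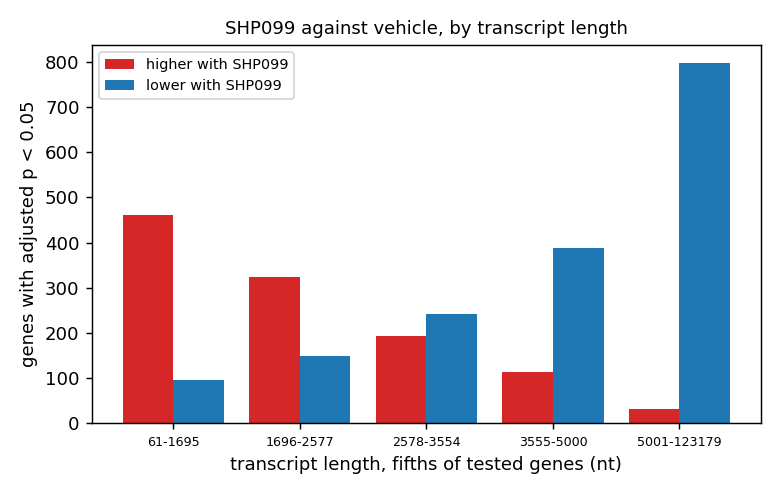
Genes with an adjusted p below 0.05 for SHP099 against vehicle, in 5 bins of tested genes by transcript length in nucleotides; red bars count genes higher with SHP099 and blue bars genes lower. Higher genes go from 460 to 32 and lower genes from 96 to 798 between the shortest and the longest bin.

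The comparison of mutant with WT vehicle cells sets out the state on which the inhibitor acts. Mutant cultures had lower levels of most measured mature neutrophil, mast cell and erythroid genes and all 11 megakaryocyte genes. They had higher levels of most MYC targets and heat shock genes. Whether the cell type genes fell within cells or fewer cells of those types were present cannot be told from bulk libraries. The megakaryocyte gene Pf4 stood at 758 ± 83.9 CPM in WT and 347 ± 49.3 CPM in mutant cells, and Cpa3 at 777 ± 29.4 and 417 ± 70.5 CPM. In edgeR, 4199 genes passed an adjusted p of 0.05, 2248 higher and 1951 lower in mutant cells, and of 551 that changed more than 2-fold, 96 were higher and 455 lower. Which direction held more genes depended on the method, with 1908 higher and 2098 lower by RLE scaling and 1963 and 2085 in DESeq2. The counts were 1432 and 1976 with the 2 groups alone. With the replicate block they were 732 and 1340, though WT and mutant libraries share only a number.

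All 11 megakaryocyte genes fell (camera adjusted p = 1.1e-16; adjusted p = 0.12 with an estimated correlation; 11 adjusted over the list alone), Gp1bb by 1.41 ± 0.15 on the log2 scale. Mast cell and basophil genes fell in 12 of 17 members, 15 adjusted over the list alone (adjusted p = 7.9e-11; adjusted p = 0.12 with an estimated correlation), with Cma1, a mast cell chymase gene, at -2.30 ± 0.21. Mature neutrophil genes fell in 11 of 17 members and rose in 1, and adjusted over the list alone 13 fell (adjusted p = 7.8e-07; adjusted p = 0.12 with an estimated correlation), with Cd177 at -1.64 ± 0.23 and Lcn2 at -0.95 ± 0.15. Erythroid genes fell in 10 of 11 members and rose in 1, also adjusted over the list alone (adjusted p = 3.4e-06; adjusted p = 0.34 with an estimated correlation), among them Gata1, a transcription factor gene of the erythroid and megakaryocyte lineages, at 86.6 ± 13.3 CPM in WT and 43.3 ± 5.5 CPM in mutant cells, and 7 fell without WT replicate 3 or without mutant vehicle replicate 1 or 3. Eosinophil genes fell in 3 of 9 members and rose in 1, also adjusted over the list alone (adjusted p = 0.0004; adjusted p = 0.12 with an estimated correlation), with the granule gene Prg2 at -1.35 ± 0.10.

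MYC targets rose in 36 of 42 members and fell in none, 37 adjusted over the list alone (camera adjusted p = 3.5e-16; adjusted p = 0.21 with an estimated correlation), with Utp20 at 0.49 ± 0.06 and Nolc1 at 0.40 ± 0.05. Heat shock genes rose in 6 of 8 members, 7 adjusted over the list alone (adjusted p = 0.0009; adjusted p = 0.12 with an estimated correlation), with Hsp90aa1 at 0.38 ± 0.04. RAS-ERK output genes were lower in mutant than in WT cells: 9 of 22 fell and none rose, also adjusted over the list alone (adjusted p = 0.0047; adjusted p = 0.38 with an estimated correlation), with Phlda1 at -1.11 ± 0.11 and Dusp4 at -0.78 ± 0.12. Without WT replicate 2 the list's adjusted p was 0.051. Of p53 targets 7 of 22 fell, 8 adjusted over the list alone (adjusted p = 0.0009; adjusted p = 0.21 with an estimated correlation), with Trp53inp1 at -0.67 ± 0.06. Of NF-kB and inflammatory genes 7 of 22 fell, and adjusted over the list alone 8 fell and 1 rose (adjusted p = 0.0036; adjusted p = 0.45 with an estimated correlation), with the chemokine gene Ccl3 at -1.25 ± 0.13. Without mutant vehicle replicate 3, 3 of these fell.

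The other 17 lists did not pass in this comparison. STAT5 targets had 3 higher and 5 lower of 11 (camera adjusted p = 0.066), with Osm at -1.04 ± 0.06. Monocyte and macrophage genes had 6 higher and 3 lower of 21 (adjusted p = 0.88), with Irf8 at 1.20 ± 0.15. Their median log2 fold change was 0.24 and their mean -0.2, and that mean includes Lyz1, the largest decrease named below. Stem and progenitor genes had 2 higher and 5 lower (adjusted p = 0.50), with Cd34 at 0.80 ± 0.09. The SHP2, receptor and RAS pathway list had 3 higher and 6 lower (adjusted p = 0.065), with the cytokine receptor gene Csf2ra at -0.93 ± 0.07. Glycolysis genes had 5 higher and 1 lower (adjusted p = 0.17), interferon response genes 3 and 4 (0.77), ATF4 stress genes 4 and 3 (0.37), oxidative phosphorylation genes 4 and 0 (0.33), G2/M genes 3 and 1 (0.10), G1/S genes 2 and 1 (0.37) and stromal genes 1 and 2 (0.56). At most 1 member in each direction was called among pro-survival BCL2 family (0.63), pro-apoptotic BCL2 family (0.88), primary granule (0.88), dendritic cell (0.56), lymphoid (0.77) and cholesterol synthesis genes (0.48). Adjusted over the list alone, these counts were the same except for STAT5 targets (4 higher, 5 lower), G1/S (1 and 0), interferon response (3 and 5), cholesterol (0 and 1), glycolysis (5 and 2) and ATF4 stress genes (5 and 3). Of the lists that did not pass, several did with 1 library left out. STAT5 targets passed without mutant vehicle replicate 3 (adjusted p = 0.025), G2/M genes without WT replicate 1 (0.034, 5 higher and 0 lower), and glycolysis and oxidative phosphorylation genes without mutant vehicle replicate 1 (0.016 and 0.026, 7 higher in each). SHP2 pathway genes passed without WT replicate 3 (0.012, 0 higher and 7 lower) and without mutant vehicle replicate 2 or 3 (0.035 in each), and by RLE scaling (0.047, 2 higher and 7 lower). Cholesterol synthesis genes had 0 higher and 4 lower by RLE scaling and also without WT replicate 3. Without mutant vehicle replicate 3, monocyte genes had 2 higher and 1 lower, interferon response genes 3 and 1, glycolysis genes 2 and 1, oxidative phosphorylation genes 1 and 0, ATF4 stress genes 3 and 1 and stromal genes 0 and 0. Without mutant vehicle replicate 2, interferon response genes had 1 and 3 and oxidative phosphorylation genes 1 and 1.

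Among the genes taken by the naming rule, the lowest in mutant cells relative to WT were Lyz1, a lysozyme gene with the close relative Lyz2, at 269 ± 71.8 CPM in WT and 1.19 ± 0.338 CPM in mutant cells (log2 fold change -7.83 ± 0.27), and Vill, an actin-binding protein gene, at 30.3 ± 8.99 and 0.223 ± 0.193 CPM (-7.15 ± 0.38). Chit1 (-3.40 ± 0.42), Mmp25 (-2.80 ± 0.40) and the erythrocyte anion exchanger gene Slc4a1 (-2.69 ± 0.74) followed, and the Slc4a1 call was lost without WT replicate 3 or mutant vehicle replicate 1 or 3 (adjusted p up to 0.07). The highest among them included the pseudogene Npm3-ps1 (3.37 ± 0.31), whose reads could be shared with its parent, and the kinase gene Alpk1 (1.88 ± 0.06). Gbp2b, an interferon-inducible GTPase gene below the 5 CPM of that rule, had no counts in the WT libraries and 1.39 to 2.93 CPM in mutant vehicle libraries. It lies within 20 Mb of Tet2 (chromosome 3, 142594847 to 142619179). In the fit without the replicate block, neither Lyz1 nor Vill passed the edgeR test for SHP099 against vehicle (adjusted p = 0.23 and 0.91).

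A further question is how far SHP099 moved the genes that differ between mutant and WT cells. Of the 4199 genotype calls, 1229 (29.3%) were also called for SHP099 in the opposite direction, 817 higher in mutant cells and lower with SHP099 and 412 the reverse, while 105 were called in the same direction. Of the 36 MYC targets called by genotype, 27 were called the other way with SHP099. This held for 5 of 8 STAT5 targets, 3 of 6 heat shock genes, 4 of 12 mature neutrophil genes (Wfdc21, Lcn2, S100a9 and Ngp), 3 of 12 mast cell genes (Cma1, Ms4a2 and Cpa3) and 2 of 11 megakaryocyte genes (Pf4 and Gp1bb), but for 0 of the 9 RAS-ERK output genes, and 8 of those 9 were also called lower in treated than in WT cells. RAS-ERK output genes were not alone in this. Called the other way were also 0 of 7 p53 targets, 0 of 7 stem and progenitor, 0 of 4 eosinophil, 1 of 11 erythroid and 1 of 7 NF-kB genes. Independent genotype and SHP099 calls of these numbers would share 292 and 172 genes in the opposite directions and 198 and 253 in the same directions. All these counts come from the fit without the replicate block. In the blocked fit SHP099 raised 16 of 17 mature neutrophil, 12 of 17 mast cell and 10 of 11 megakaryocyte genes, with none lower. RAS-ERK output genes there had 1 higher and 14 lower of 22. These lists moved in the same directions in both fits, while the counts of called members depended on the fit.

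The correlation of the log2 fold changes across genes was -0.283 and their covariance -0.0407. Both comparisons use the mutant vehicle libraries with opposite sign, and 20 simulations with no effect gave a mean correlation of -0.499 and a mean covariance of -0.0239 (range -0.0324 to -0.0203), a difference of covariances of -0.0168. Allowing for the pairing, the shared libraries alone would give a covariance of about -0.00945 on the scale of log2 CPM, where all libraries gave -0.0367. With 3 vehicle libraries the controls could not be split into groups of at least 2. With 1 vehicle library against WT and the other 2 pairs for SHP099, the covariances were -0.0343, -0.0242 and -0.0236. Part of the covariance over all libraries may come from the shared controls. The count of 1229 was 794 without mutant vehicle replicate 1, 721 without mutant vehicle replicate 3 and 759 without SHP099 replicate 3.

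**Figure D3:**
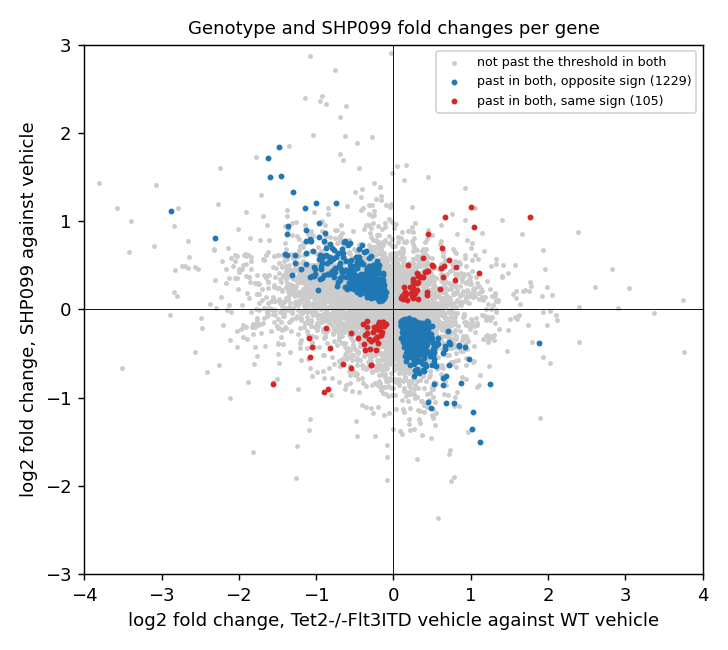
Log2 fold change of each gene for mutant against WT vehicle cells (x axis) and for SHP099 against vehicle in mutant cells (y axis), with genes past an adjusted p of 0.05 in both coloured blue for opposite signs (1229) and red for the same sign (105). Grey points are the other tested genes, and 9 genes lie outside the axes.

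SHP099-treated mutant cells were also set against WT vehicle cells, where genotype and treatment differ together. RAS-ERK output genes were lower in 17 of 22 members and higher in none, 18 adjusted over the list alone (camera adjusted p = 1.8e-10; adjusted p = 0.14 with an estimated correlation), with Dusp6 at 29.7 ± 0.333 CPM against 56 ± 5.26 CPM in WT cells. MYC targets were divided, with 6 higher and 6 lower of 42 (adjusted p = 0.49), and Nolc1 was at 265 ± 2.36 CPM in treated and 266 ± 8.53 CPM in WT cells. The 11 megakaryocyte genes were all lower (adjusted p = 3.3e-07; adjusted p = 0.56 with an estimated correlation; 11 adjusted over the list alone), with Pf4 at 497 ± 44.2 CPM. Erythroid genes were lower in 9 members (10 adjusted over the list alone) and higher in none, eosinophil genes lower in 5 and higher in 1, mast cell genes 8 and 1, NF-kB genes 10 and 1 and p53 targets 9 and 1 (adjusted p = 6.5e-05, 1.4e-05, 0.004, 0.0016 and 0.0075; 0.57, 0.068, 0.57, 0.57 and 0.56 with an estimated correlation). Oxidative phosphorylation genes were higher in 14 and lower in 1 (8 and 0 without SHP099 replicate 3), monocyte genes 11 and 1 and lymphoid genes 3 and 0 (adjusted p = 6.3e-05, 0.02 and 0.038; 0.57, 0.57 and 0.56 with an estimated correlation). Adjusted over the list alone, 1 more was higher among mast cell, NF-kB and lymphoid genes, 1 more lower among monocyte genes and 1 more in each direction among p53 targets. Monocyte genes did not pass without WT replicate 2 or 3 (adjusted p = 0.2 and 0.25), nor lymphoid genes in 8 of 9 fits with 1 library left out. The 16 other lists, apart from MYC targets, did not pass (adjusted p = 0.2 to 0.94). MYC targets had 10 higher and 6 lower and passed without WT replicate 3 (adjusted p = 0.047), and primary granule genes passed without SHP099 replicate 2 (adjusted p = 0.026). In edgeR 4209 genes passed, 2045 higher and 2164 lower, and 2053 (48.9%) of the 4199 genotype calls were called in the same direction. Log2 fold changes here also went with transcript length (Spearman's correlation -0.221 across 12801 genes). The lists of this comparison, oxidative phosphorylation genes among them, were not tested with that trend removed.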

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

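The length and GC corrections and the block with an estimated correlation were chosen after the results were seen. For SHP099 against vehicle, the replicate block gave 5563 genes in place of 2890, and 5242 with the length and GC trend also removed. Leaving out 1 library gave 1767 to 2976 genes. The other alternatives gave counts within 1.5 times the reported one (RLE 2895, DESeq2 3190, no filter 2603, 1 CPM filter 2963, 2 groups alone 2750, trend removed 2202). For mutant against WT vehicle, where the samples share only a number (correlations of -0.072, -0.11 and -0.13 for the same number), the replicate block gave 2072 genes in place of 4199, and leaving out 1 library 2879 to 3886. For treated mutant against WT the block gave 3024 in place of 4209, and leaving out 1 library 2826 to 4403; no WT library correlated best with its own number. The count of genes moved the other way by SHP099 was 1229, 1079 with the block, 721 to 1070 with 1 library left out and 942 with 2 groups alone. With an estimated correlation, 0 of 27 lists passed for SHP099 (camera; 2 at an unadjusted p under 0.05; fry called 8), 0 with the replicate block and an estimated correlation (3 unadjusted), and 0 for genotype (5 unadjusted; fry called 14), in place of 8 and 10; leaving out 1 library gave 8 to 11 and 9 to 12. The 8 lists that fry called for SHP099 were not the same 8 that passed camera. Monocyte, megakaryocyte and oxidative phosphorylation genes did not pass fry (adjusted p = 0.07, 0.1 and 0.066). STAT5 targets, pro-survival BCL2 family and lymphoid genes passed fry (adjusted p = 0.043, 0.043 and 0.018) but not camera. The cause of the shifts in these counts was not tested. The block changed no other camera call among the SHP099 lists. All 8 lists passed camera in each fit with 1 library left out, as did 9 of the 10 for genotype, and RAS-ERK output genes in 8 of 9 fits (highest adjusted p = 0.051, without WT replicate 2). Of comparisons of a named gene with an alternative, 1373 for SHP099 kept their side of the threshold, 92 lost it and 30 gained it; for genotype 1540 kept it and 124 lost it, and none changed sign with a call. Depth limits low genes such as Flt3, at 47 to 127 counts per library.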

Other observations

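The gene families in the next paragraphs were defined by symbol after the calls had been seen, and the test of chromosome segments was prompted by genes already seen. Its repeats without those genes, the covariances with no vehicle library in both comparisons, the windows and the repeats without SHP099 replicate 3 and the corrections for length were also chosen after results had been seen. With SHP099, nucleoporin genes were lower in 12 of 20 members (camera adjusted p = 1.8e-09; adjusted p = 0.078 with an estimated correlation), genes of RNA polymerases I and III in 5 of 14 (adjusted p = 0.00034; 0.16 with an estimated correlation) and cytosolic tRNA synthetase genes in 7 of 17, or 4 without SHP099 replicate 3 (adjusted p = 0.00067; 0.16 with an estimated correlation). In mutant against WT cells these families were higher, with 15 nucleoporin, 8 polymerase (5 without SHP099 replicate 3) and 5 tRNA synthetase genes called (camera adjusted p = 8.1e-06, 0.0032 and 0.0089; adjusted p = 0.35, 0.35 and 0.38 with an estimated correlation). Families that did not pass as lower with SHP099 were higher by genotype too, with 12 of 82 ribosomal protein, 27 of 74 mitochondrial ribosome, 16 of 38 proteasome (1 lower) and 10 of 20 heterogeneous nuclear RNP genes (3 of these 20 lower with SHP099) (camera adjusted p = 0.0089, 0.0004, 0.0012 and 0.0032; 0.68, 0.54, 0.54 and 0.35 with an estimated correlation). By genotype small nucleolar RNA genes also passed, with 7 higher and 1 lower, and mast cell protease genes, with 3 of 4 lower (adjusted p = 0.0089 and 0.012; 0.54 and 0.35 with an estimated correlation). The other 6 families did not pass by genotype. Without SHP099 replicate 3, 4 ribosomal protein (7 by RLE scaling), 6 heterogeneous nuclear RNP (none lower with SHP099) and 4 small nucleolar RNA genes were higher by genotype, and histone genes passed there as lower (adjusted p = 0.033, 4 lower). All 5 KMT2 histone methyltransferase genes, whose transcripts are long, were lower with SHP099 (adjusted p = 3.9e-11; adjusted p = 0.048 with an estimated correlation, 0.14 with the block). Their median log2 fold change in the blocked fit was -0.55 (SD 0.14), and -0.18 (SD 0.1) with the length trend also removed.

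Vacuolar ATPase genes, which acidify the lysosome, were higher with SHP099 in 6 of 15 members (camera adjusted p = 0.00014; adjusted p = 0.15 with an estimated correlation) and cathepsin genes in 3 of 14 (adjusted p = 0.00067; 0.16 with an estimated correlation), in each case with no member lower. Small nucleolar RNA genes, which lie within host genes, were lower in 34 of 62 members with a median log2 fold change of -0.88, and in the blocked fit of the 56 with a correction -0.89 (SD 0.39) before and -0.52 (SD 0.38) after the length trend was removed (adjusted p = 1.1e-13; 0.11 with an estimated correlation). Histone genes, most of whose transcripts have no poly(A) tail, were higher in 8 of 39 members (adjusted p = 5.2e-06; 0.47 with an estimated correlation), but in 2 without SHP099 replicate 3, the library with 4.33% of Rn45s, where their median went from 1.4 to 0.45. Ribosomal protein genes, which have short transcripts, were higher in 8 of 82 members and lower in 1 (adjusted p = 4.4e-06; 0.47 with an estimated correlation), and with the length trend removed in the blocked fit the list no longer passed (adjusted p = 0.14). Without SHP099 replicate 3, 3 were higher and none lower, and by RLE scaling 13 were higher and 1 lower. These directions were the same with RLE scaling. Of the 15 families tested, mast cell protease genes also passed, with 1 of 4 higher (adjusted p = 0.0076; 0.17 with an estimated correlation), and 5 did not pass: mitochondrial ribosome (adjusted p = 0.73; lower with 0.00083 once the length trend was removed in the blocked fit), proteasome (0.14), heterogeneous nuclear RNP (0.10), Schlafen (0.95) and eosinophil-associated RNase genes (0.80).

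Long transcripts were called lower and short ones higher with SHP099, and this trend could have made the calls. Removing the length and GC trend in the blocked fit left 94.2% as many called genes, 93.3% of the called RAS-ERK output genes and 96.9% of the called MYC targets, which argues against the trend as the whole of these results. The 94.2% compares totals, not the same genes. In the fit of all libraries the correction took the count from 2890 to 2202. There 18 named genes lost their call, 69 kept their side of the threshold and 1 gained a call. The trend was not due to the library richest in Rn45s alone, since without SHP099 replicate 3 the correlation with length kept 89.1% of its size. In the blocked fit the correction did end the camera call of oxidative phosphorylation genes, whose members' median log2 fold change went from 0.086 (SD 0.12) to -0.0049 (SD 0.10). RNA integrity or library preparation that differed with treatment, and an effect of the inhibitor on long transcripts, stay open and were not tested.

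Genes that differed by genotype tended to lie on the other side of 0 under SHP099. Removing the length and GC trend kept 91.6% of the covariance, which argues against that trend. The covariance of -0.0407 lay below all 20 simulations in which the shared vehicle libraries alone act, but was 1.70 times their mean, under the 2 times set in advance, a bound that decides little because the simulations leave out the pairing (with it the estimate is -0.00945, against -0.0367 for all libraries on that scale). With no vehicle library in both comparisons all 3 covariances stayed below 0, with a mean of -0.0273, 74.4% of the latter, which argues against the shared libraries as the whole cause. The -0.00945 and the -0.0273 are 2 parts of the same -0.0367 and are not separate evidence. As point estimates they leave 74.4% outside the shared libraries. How exact that share is, and how far it is a partial return of mutant cells toward WT levels, cannot be told here. The estimates have no interval, and separate vehicle cultures would be needed for that share. No WT cells received SHP099, so a return toward WT levels cannot be told from an effect that WT cells would also show.

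Alpk1, Adgrl2 and Adgrl4, all on chromosome 3 near Tet2, were among the genes with the largest genotype differences by the naming rule. This prompted the hypothesis that a chromosome segment inherited with the Tet2 allele may carry strain variants. Within 20 Mb of Tet2, 48 of 120 tested genes were called, an odds ratio of 1.44 (95% interval 0.978 to 2.11, one-sided Fisher's exact p = 0.032), which passed the bound set in advance. The largest difference among these 48 was that of Gbp2b (log2 fold change 9.41 ± 0.86, SE), which is not 1 of the 3 prompting genes. Without the 3 prompting genes the odds ratio was 1.35 (0.909 to 2, one-sided Fisher's exact p = 0.07), and the genes over 2-fold went from 11 of 120 (odds ratio 2.35, 1.13 to 4.42, p = 0.011) to 8 of 117 (1.71, 0.717 to 3.52, p = 0.11). Of 136 windows of the genome, and without the 3 genes, 140 to 160 Mb of chromosome 3 ranked 2 by share of called genes (55.1%), after 1 on chromosome 10 (59%), and 3 by share over 2-fold (10.2%). Whether a segment came with the Tet2 allele cannot be told apart from chance here, since both tests lose a p under 0.05 without the 3 genes, nor can a segment with the Flt3 allele (odds ratio 0.872, 0.64 to 1.18), and single genes near Tet2 are uncertain as effects of the mutations.

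Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. In edgeR the real split was the 1 split of 10 with the highest count, with 2890, 4199 and 4209 genes for the 3 comparisons, and the highest of the other splits gave 0 in each (1013, 775 and 632 genes at an unadjusted p under 0.05; DESeq2 was not run on them). For SHP099, 3 of the other 9 splits part all 3 pairs as the real one does, and the other 6 part 1 pair. In each of the other splits the real difference lies within the groups and raises the estimated spread. A count of 0 there was therefore likely from the start and decides little.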
